A study of Nicotiana tabacum with 8 samples.

How the data were processed

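RNA was measured in tobacco (Nicotiana tabacum) BY-2, a fast-growing suspension line of undifferentiated plant cells, harvested 3 days after subculture. Per the labels' protocols, cells were collected on a 40 µm mesh and washed in 0.5 M mannitol. One part was frozen at once, and the rest was digested for 2 h at 26 °C in 1.5% cellulase and 0.5% macerase, which remove the cell wall and leave protoplasts. The 8 samples were 3 bulk libraries of cells before digestion (unprotoplasted), 3 bulk libraries of protoplasts, and 2 single-cell libraries of protoplasts made with the 10x Genomics version 3 gene expression kit. Samples were assigned to groups from their titles. In the bulk table, column prefixes were matched to the titles by initial and replicate number.

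The bulk table that the authors deposited gives read counts per gene, with no normalization, in 6 columns. It also holds the authors' normalized values, a signal made by dividing each count column by 1 factor per library. The largest relative deviation from a constant factor was 5e-15. The authors' log2 fold changes and their adjusted p-values complete the table, and these are quoted only as the authors' deposited table. Both single-cell tables deposited by the authors hold unnormalized UMI counts (unique molecular identifiers, 1 per captured RNA molecule) per gene and cell barcode. The submitters' processing notes name Cell Ranger 4.0.0, STAR, featureCounts 2.0.2 and DESeq2 1.28.1. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Bulk reads accumulate along the whole transcript and so grow with gene length, whereas UMIs do not, and multi-copy genes of this allotetraploid species can share reads in either assay.

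Genes carry running numbers (gene_1 and so on) in every table. None of them (0 of 85570) occurred in the RefSeq gene table of the species used here, and the files do not pair them with names. The gene lists, cell-type markers and cell-cycle classes that had been fixed before the data were examined could therefore not be matched, and the tests that rest on them were not run. The naming rule, also set before the data were examined, asked for a product description, which no ID has. With that condition left out, 2 IDs that rose and 2 that fell are named. They had the largest fold changes among genes past an adjusted p of 0.05 whose groups did not overlap and whose mean over the distinct libraries was at least 10 CPM. CPM are counts scaled to a common library total. For the bulk means of single genes these totals were first adjusted by TMM, the scaling used in the test.

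The count columns of protoplasted replicates 2 and 3 were identical for every gene. Between the other libraries of a group at least 61323 genes had different counts, and the chi-square per gene over genes with 20 or more reads lay between 2.43 and 7.54 against 0 for the identical pair. The identical columns differed by less than the sampling noise and were counted as 1 sample, which left 3 unprotoplasted and 2 protoplasted libraries. The design fixed before the data were examined had 3 against 3 libraries, and a fit on all 6 columns, added once the identical columns had been seen, is given as an alternative.

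Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, the filterByExpr filter, no replicate block and Benjamini-Hochberg adjustment at 0.05. On data simulated from these libraries (47363 genes, 200 of them changed) it recovered 95% of 4-fold and 49% of 2-fold changes and made 9 false calls among 153. The simulated changes were split equally between up and down. In the data 16056 genes were called and rises were larger than falls, so these rates do not carry over to the real comparison. Alternatives were DESeq2 1.42.0, voom in limma 3.58.1, other scalings, no filter, each library left out, and a replicate block. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

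Barcodes with at least 1000 UMIs and 500 genes were kept as cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were centred within each library, and 30 principal components, 15 neighbours and Leiden clustering at a resolution of 0.5 (leidenalg 0.10.2) gave clusters, which are named by number. In simulated cells of 3000 UMIs each, the procedure returned 4 clusters for 4 groups that differed 8-fold in 100 genes per group. It returned 1 cluster for a homogeneous group. Real cells differed widely in depth, so the simulation does not show how depth or smaller differences affect the clusters. No cells were removed as doublets, and free RNA in the droplets was not estimated. A score from simulated pairs of barcodes was used in 1 alternative, which left out the 449 highest-scoring barcodes of library 1 and 161 of library 2 at a rate set beforehand, and doublets of alike cells cannot be seen this way. With 2 libraries of a single condition no test between libraries was possible, and shares of cells have exact Clopper-Pearson 95% intervals that cover counting error only.

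Because annotated lists were unavailable, gene groups were taken from the data after the tables had been seen. Each library was clustered alone, the 40 genes with the largest fold in each cluster of at least 50 cells (at 20 CPM or more in that library) formed a group, and the group was tested in the other library. The test was the correlation across cells between the scores of both parts of a group split at random into equal parts, as the median of 5 splits, beside 100 random lists matched on expression. Cells thinned to 1614 UMIs, which left out 1198 shallower cells of library 2 and 0 of library 1, served as an alternative. Levels in single-cell and bulk libraries were compared as log2(CPM + 1).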

Results

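The data comprised bulk and single-cell transcriptomes of tobacco BY-2 suspension cells. The 3 unprotoplasted bulk libraries held 16509777, 16529365 and 16167906 counted reads, and the 2 distinct protoplasted libraries held 15573880 and 16040944. The columns of protoplasted replicates 2 and 3 were identical, differed by less than the sampling noise and were counted as 1 sample. The single-cell libraries held 7489 and 4500 barcodes, 11989 in all, where the study states more than 12000. They carried 53770570 and 38905921 UMIs. Genes are given by the running numbers in the tables, which could not be paired with names, so no pathway, cell type or cell-cycle phase is assigned.

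The first comparison asked how the transcriptome differed after protoplasting, in protoplasted against unprotoplasted bulk libraries. Unprotoplasted cells were frozen at once and protoplasts had spent 2 h at 26 °C in enzymes, and with no library incubated without enzymes here, wall removal, incubation and enzyme exposure cannot be separated. The difference was broad and larger upward than downward. Of 47363 genes tested, 8174 were higher and 7882 lower in protoplasts, together 33.9% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 3 against 2 libraries). The numbers of rising and falling genes were close, but the sizes were not. Of the rising genes 2412 (29.5%) were at least 4-fold higher, whereas 405 of the falling genes (5.14%) were at least 4-fold lower. At a fitted change of 16-fold or more, 732 genes were higher and 23 lower, although fitted folds of genes with few reads in a group depend on the prior count. The median log2 fold change was 1.19 among rising and -0.86 among falling genes.

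Among genes with a mean of at least 10 CPM, the largest rises were those of gene_20527 and gene_37175. Gene_20527 was nearly silent before digestion, with 2 reads over 3 libraries, both in replicate 3, and stood at 32.5 ± 4.01 CPM in protoplasts (SD, n = 2). Its ratio of pooled CPM, on library totals without TMM, was 760 with a 95% counting interval of 210 to 6281. Without unprotoplasted replicate 3, which leaves 0 reads before digestion, its fitted log2 fold change moved from 9.43 to 12.01 and is no bound. For gene_37175 there were 3 reads before digestion and 30.4 ± 0.600 CPM after it (SD, n = 2), with a ratio of pooled CPM of 473 (161 to 2296). Its fitted log2 fold change of 8.83 became 8.30 without unprotoplasted replicate 1 and 9.66 without unprotoplasted replicate 2. The largest falls were far smaller. Gene_24631 went from 17.6 ± 2.55 CPM (SD, n = 3) to 2.60 ± 0.438 CPM (SD, n = 2), a log2 fold change of -2.76 ± 0.21 (SE), with an edgeR adjusted p of 1.81e-12. Gene_16071 went from 105 ± 8.63 CPM (SD, n = 3) to 16.3 ± 0.210 CPM (SD, n = 2), a log2 fold change of -2.68 ± 0.13 (SE), with an edgeR adjusted p of 3.67e-17. The authors' deposited table gives -2.70 and -2.68 as the log2 fold changes of gene_24631 and gene_16071.

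**Figure D1:**
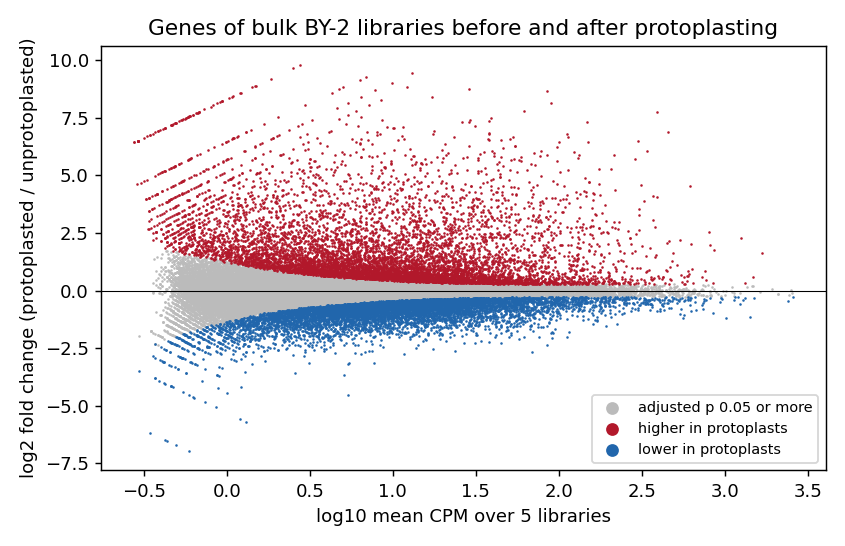
Log2 fold change of protoplasted over unprotoplasted bulk libraries against the log10 mean CPM over the 5 distinct libraries, with 1 point per tested gene (edgeR). The 8174 rising genes (red) reach further from 0 than the 7882 falling genes (blue), and grey genes had an adjusted p of 0.05 or more.

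Genes at least 4-fold higher in protoplasts took 1.27% ± 0.0132 of the reads before digestion (SD, n = 3) and 10.4% ± 0.0299 after it (SD, n = 2). Genes at least 4-fold lower went from 0.254% ± 0.0198 (SD, n = 3) to 0.0486% ± 0.00162 (SD, n = 2). These gene sets were chosen on the same libraries, so the shares measure the size of the difference and do not test it. Scaling set the balance of directions. With library size alone in place of TMM, the median of all genes moved to a log2 fold change of -0.12, and 39.3% of the called genes were higher in protoplasts instead of 50.9%. Without protoplasted replicate 2, 10641 genes were called (4953 of them lower) in place of 16056 (7882 lower). The authors' deposited table lists 8948 genes as higher and 8192 as lower at an adjusted p under 0.05, counts that DESeq2 gave here with all 6 columns, while DESeq2 on the 5 distinct libraries called 6547 higher and 5931 lower.

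The second set of measurements described how protoplasts of the same culture age differed from cell to cell, which the series title relates to the phase of the cell cycle. Depth was uneven. In library 1 the median was 4390 UMIs and 2819 genes per barcode, and the lowest barcode had 1725 UMIs. In library 2 the median was 4711 UMIs and 2795 genes, and barcodes began at 1002 UMIs. Library 2 fell into a shallow and a deep part, with 2282 of its 4493 kept cells (50.8%, 95% interval 49.3 to 52.3) under 5000 UMIs at a median of 1563, and the rest at a median of 15129. In library 1, 4206 of 7489 cells (56.2%, 55.0 to 57.3) were under 5000 UMIs, at a median of 2941, and the others had a median of 9763.

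**Figure D2:**
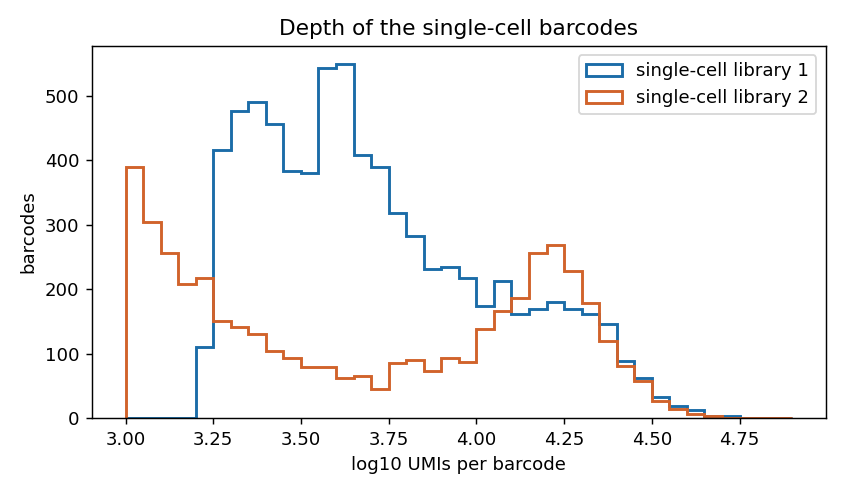
Number of barcodes against log10 UMIs per barcode in the 2 single-cell libraries, for barcodes with at least 1000 UMIs and 500 genes. Library 2 has a shallow and a deep mode, with medians of 1563 and 15129 UMIs below and above 5000, and library 1 begins at 1725 UMIs.

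Summed over cells, the 2 single-cell libraries ranked genes alike, with a Spearman rho of 0.953 across genes. They nevertheless differed more than the 2 distinct bulk protoplast libraries did. These were the most alike of the distinct bulk libraries, with a chi-square per gene of 2.43, and unprotoplasted libraries were not compared in this way. Of 14491 genes with a mean of at least 10 CPM, 340 were at least 4-fold higher in library 2 and 212 in library 1, together 3.81%. Between the 2 distinct bulk protoplast libraries 1 of these 14491 genes was at least 4-fold apart, and likewise 1 of the 16207 genes with a mean of at least 10 CPM in those libraries (0.00617%). With cells thinned to 1614 UMIs, and 1198 shallower cells of library 2 left out, 296 and 234 of the 14491 genes were at least 4-fold apart in these directions. With 1 library on each side there was no test of these differences.

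Both single-cell libraries lay closer to bulk protoplasts than to unprotoplasted cells. In library 1 the Spearman rho across genes was 0.743 and 0.744 with the 2 protoplasted libraries and 0.709 to 0.712 with the 3 unprotoplasted ones. In library 2 the corresponding values were 0.715 with each protoplasted library and 0.682 to 0.687 with unprotoplasted ones. IDs that the bulk table does not list entered at a bulk level of 0, and with these 5590 and 5101 IDs left out the values were 0.746 with each protoplasted library and 0.706 to 0.709 with unprotoplasted ones in library 1, and 0.718 to 0.719 and 0.679 to 0.686 in library 2. Genes are not independent replicates, so no p-value is attached. For the genes raised at least 4-fold in bulk protoplasts the median share of a cell's UMIs was 13.3% in library 1 and 15.3% in library 2, and all 7489 and all 4493 cells exceeded the highest unprotoplasted bulk library. This sets UMIs against reads, which grow with gene length, and free RNA in the droplets, which would carry the same transcripts, was not estimated, so the share does not show that each cell expressed these genes. The mean of the 2 medians was 14.3% ± 1.39 (SD, n = 2). Pooled over cells the share was 12.8% and 14.8%, against 10.4% of reads in bulk protoplasts.

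Cells differed in this share by more than sampling allows. The standard deviation between cells was 5.48 percentage points in library 1 and 4.22 in library 2, of which 5.45 and 4.16 remained after the binomial sampling variance was removed. The middle 90% of cells ranged from 5.38% to 23.3% in library 1 and from 8.20% to 22.2% in library 2. Shallow cells had the higher share, with medians of 14.4% under 5000 UMIs and 11.8% above in library 1, and 16.3% and 14.3% in library 2. Thinned to 1614 UMIs, the 7489 cells of library 1 had a median of 13.3% and the 3295 deep enough cells of library 2 had 14.5%, with the 1198 shallower ones left out. Random thinning leaves the expected share of a cell unchanged, so these values do not test the relation to depth. Genes at least 4-fold lower in bulk protoplasts took a median of 0.136% and 0.164% of UMIs per cell, between the bulk levels of protoplasts and of unprotoplasted cells. These genes were chosen for low levels in the same bulk protoplasts, and UMIs are set against reads. The values therefore do not show that the captured cells kept more of these transcripts.

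**Figure D3:**
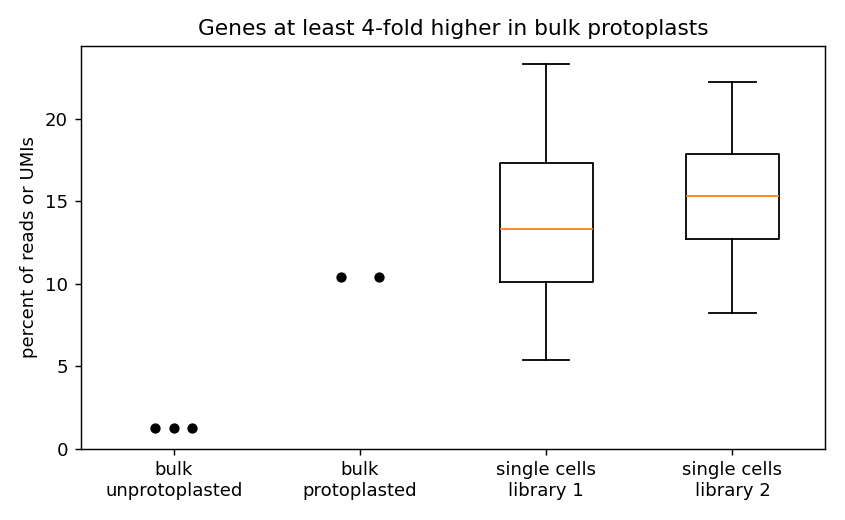
Percent of reads (bulk, 1 point per distinct library) or of UMIs per cell (single cells, boxes for quartiles, lines for medians and whiskers from the 5th to the 95th percentile) from the 2412 genes at least 4-fold higher in bulk protoplasts. Bulk libraries stand at about 1.27% before and 10.4% after protoplasting, and the median cell at 13.3% and 15.3%.

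Clustering of both libraries together gave 10 clusters, and some were found mostly in 1 library. Cluster 1 held 32.7% of library 1 (95% interval 31.6 to 33.8) and 26.9% of library 2 (25.6 to 28.2). Cluster 6 held 6.06% (5.53 to 6.63) and 4.23% (3.66 to 4.86), and cluster 10 held 0.881% (0.682 to 1.12) and 1.00% (0.731 to 1.34). By contrast, cluster 3 held 37.3% of library 2 and 0.240% of library 1, and clusters 8 and 9 held 10.5% and 9.73% of library 2 and 0.0401% each of library 1. Clusters 5 and 7 also held cells of both libraries, with 9.12% (8.48 to 9.79) and 5.70% (5.19 to 6.25) of library 1 and 3.72% (3.18 to 4.31) and 3.36% (2.85 to 3.93) of library 2. Clusters 2 and 4 held 23.7% and 21.5% of library 1 and 1.98% and 1.18% of library 2. A cluster of this kind may be the library and not a cell state, and the shares of clusters were not compared further. Cells thinned to 1614 UMIs, with the shallower ones left out, gave 23 clusters with an adjusted Rand index of 0.0285 to these 10 when variable genes were chosen anew, and 8 clusters with an index of 0.556 when the variable genes of the full data were kept.

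**Figure D4:**
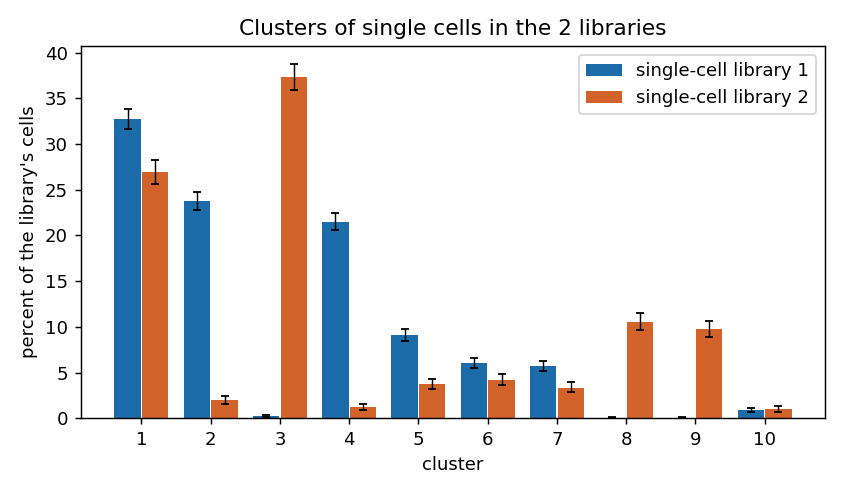
Percent of each single-cell library's cells in each of 10 clusters, with exact 95% intervals that cover counting error only. Clusters 1, 5, 6, 7 and 10 hold cells of both libraries, with 9.12% and 3.72% in cluster 5, and clusters 3, 8 and 9 are almost confined to library 2 (0.240%, 0.0401% and 0.0401% of library 1).

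The clusters differed in how many of their 40 leading genes were raised at least 4-fold in bulk. Of the leading genes tested in bulk, 19 of 39 (48.7%) were raised in cluster 7, 18 of 39 (46.2%) in cluster 5, 14 of 38 (36.8%) in cluster 4 and 12 of 37 (32.4%) in cluster 2, against 10.1% of the 8015 background genes. The share was 5.13% in cluster 1, 12.1% in clusters 3 and 9, and 10.0% in cluster 8, where 20 of the 40 genes were tested. Clusters 6 and 10 had 0 such genes among 40 and 39. Clusters 2 and 4 were mostly cells of library 1, and clusters 3, 8 and 9 almost all of library 2. The leading genes of these clusters may therefore reflect the library. Clusters 4 and 8, and clusters 2 and 9, held most cells of pairs matched across libraries below, yet their shares were unlike. Genes are not independent replicates and the leading genes define the clusters, so no p-value is attached. The genes of cluster 6 had a median log2 fold of 3.93 over the other cells, the second highest after 4.53 in cluster 8. In cells of cluster 10 the raised genes took a median of 4.89% (library 1) and 6.64% (library 2) of UMIs, in cluster 6 they took 9.25% and 12.9%, and in cluster 4 they took 18.8% and 17.3%. In library 2 cluster 4 held only 53 cells, and cluster 7 was higher at 17.6%. Median UMIs were 7676.5 and 4330 in cluster 10, 7336.5 and 6759.5 in cluster 6, and 2998 and 2655 in cluster 4. Shallow cells had the higher share, so cluster and depth are not separated for cluster 4. In library 1 cluster 5 had a depth like that of clusters 6 and 10 (median 6981 UMIs) but a share of 16.1%. In library 2 cluster 10 was shallower than cluster 6 and had the lower share. These values argue against depth alone for the low share of cluster 10. Raised genes helped to form the clusters, so these shares are descriptive. When genes changed at least 4-fold were left out before clustering, 8 clusters were found, with an adjusted Rand index of 0.798 to the full clustering.

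Part of the heterogeneity recurred between libraries when each was clustered alone. Library 1 gave 7 clusters and library 2 gave 8, and 6 of them were each other's best match in the log2 profile of 6547 genes. The correlations of matched clusters ranged from 0.560 to 0.873, while 20 shufflings of the cluster labels reached at most 0.199. Shuffled labels give random groups of cells, so they do not test which clusters match. The weakest pair, at 0.560, was close to its next best match at 0.457. The library 1 cluster without a reciprocal match (421 cells) reached 0.596 with its best and 0.579 with its next best library 2 cluster. Both values lay above the weakest matched pair. Clusters of library 2 with 1547 cells (34.4% of the library, its largest) and 67 cells (1.49%) were the best match of no library 1 cluster. The pair with the highest correlation joined cells that the joint clustering had placed in cluster 4 (95.1% of the library 1 cells) and in cluster 8 (91.1% of the library 2 cells). In 1 other matched pair most cells also stood in different joint clusters (2 and 9), while in the remaining 4 pairs the joint cluster with the most cells was the same, although in 1 of these it held 43.3% of the library 2 cells. All 7 gene groups found in library 1 varied together across the cells of library 2, with split-half correlations from 0.229 to 0.740, each above the highest of 100 expression-matched random lists. All 8 gene groups found in library 2 did so in library 1, with correlations from 0.282 to 0.867. The highest belonged to the group of cluster 6 cells, at 0.867 in library 1 against at most 0.479 for random lists, and the corresponding group from library 1 reached 0.593 in library 2 against 0.449. Neither of these 2 groups held a gene raised at least 4-fold by protoplasting.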

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

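Gene IDs that the bulk table used here does not list (15280 of them) take no part in the comparison between bulk libraries but carried UMIs in the single-cell libraries. In library 1, 5590 of these IDs had UMIs, 2385 of them more than 3, and together they took 0.712% of all UMIs. In library 2, 5101 had UMIs, 2243 of them more than 3, and they took 0.913%. With no control library for this signal, the reference was the limit that a count of 0 allows (3 counts). No single ID dominated, since the most abundant took 7.75% of these UMIs in library 1 and 5.77% in library 2.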

How the results depend on the processing

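The tests on all 6 deposited columns, the block with number 3, the thinned, deep-cell and doublet clusterings, the gene groups and the correlations over listed IDs were chosen after seeing the data, and the thinned clustering on the variable genes of the full data only after the first thinned one had given 23 clusters. The bulk call counts stayed within 1.5 times the reported ones under other scalings, no filter, DESeq2, limma-voom and all 6 columns (20543 genes with edgeR, 17140 with DESeq2), and the 4 named genes kept their direction and side of the threshold throughout, although the fitted log2 fold change of gene_20527 moved from 9.43 to 12.01 without unprotoplasted replicate 3, which holds its only 2 reads before digestion. Leaving out each distinct library in turn gave 10641 to 16566 changed genes, 5688 to 8511 higher, 4953 to 8382 lower, 4111 to 4913 at least 2-fold higher and 2611 to 3307 at least 2-fold lower. The lowest total (10641, with 4953 lower) came without protoplasted replicate 2, and the lone protoplasted library was then assumed to vary like the others. With the replicate block on numbers 1 and 2, 15981 genes were called, 14528 of them shared with the reported 16056 in the same direction, and with the identical columns taken as number 3 the block called 12508. Same-numbered libraries did not deviate together (correlations of deviations -0.06 and -0.0013), and the samples share only a number. Among genes with CPM of at least 1 in both assays, the mean Spearman rho with bulk protoplasts fell from 0.729 to 0.666 and with unprotoplasted cells from 0.697 to 0.609. It was 0.715 and 0.743 (protoplasts), or 0.684 and 0.711 (unprotoplasted), with either single-cell library alone, and 0.732 and 0.695 over IDs listed in the bulk table. A 2-fold limit raised the share of UMIs from raised genes from 14.3% to 21.9%, and single libraries gave 13.3% and 15.3%. The 10 clusters became 7 and 8 with single libraries, 14 at a resolution of 1 (adjusted Rand index 0.640), 8 in cells of at least 5000 UMIs (0.570) and 11 without the highest doublet scores (0.733). Thinning to 1614 UMIs gave 23 clusters with an adjusted Rand index of 0.0285 when variable genes were chosen anew, but 8 clusters with an index of 0.556 when the variable genes of the full data were kept, so the larger number goes with choosing variable genes anew. The mean split-half correlation of gene groups fell from 0.544 to 0.418 in thinned cells, where 14 of 15 groups still exceeded all random lists, and each test library alone gave 0.530 and 0.559. The gene list tests, cell-cycle classes and clustering without cell-cycle genes were not run, because the IDs have no names.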

Other observations

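In this part the tests of a shift between the assays, of gene length and of a few abundant genes were chosen after the result was seen, as were the level-matched reference for rho, the distant range for ID differences of 1 and 2 and the requirement that the excess be absent at a difference of 2. Of 10 splits of the 5 distinct bulk libraries into 3 and 2, only 1, the real one, called as many as 16056 genes by edgeR, and the highest of the others called 0. The splits are too few for a share under 0.05. Every other split also put protoplasted and unprotoplasted libraries into the same group, which widens the spread within it. Their 0 calls therefore say little about chance.

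Genes raised at least 4-fold in bulk protoplasts were examined for a still higher level in single cells, and this held for their summed share (12.8% and 14.8% of UMIs against 10.4% of reads) but not for the median gene. The median log2 ratio of single-cell over bulk protoplast CPM was -0.45 and -0.49, at percentile 99.94 of level-matched lists in library 1 and 1.06 in library 2. A shift of the assay common to genes of one level predicted a percentile within the central 95% in both libraries. A still higher level predicted a percentile above that range in both. The values lay outside it on opposite sides, so neither prediction was met and the shift stays open for the median raised gene. Genes lowered at least 4-fold lay at percentiles 99.82 (library 1) and 99.18 (library 2) of their matched lists. Leaving the range was therefore not particular to raised genes. The summed share was not compared with matched lists, so for the share this shift is left open too. A response that had gone further in the captured cells predicted a ratio (on protoplasted replicate 2) that rises with the bulk fold (from replicate 1), with rho above 0.1, but across the 2412 genes Spearman's rho was -0.195 in library 1 and -0.245 in library 2, and ratios drawn from genes of the same level that were not raised gave -0.172 (95% of 1000 draws -0.211 to -0.134) and -0.239 (-0.277 to -0.203), so level alone gives such values, the bound of 0.1 was unsuited and the explanation stays open. Leaving out the 10 raised genes with the most UMIs in the other library changed the excess from 2.41 to -0.412 percentage points in library 1. In library 2 it went from 4.41 to 2.40. Both libraries ranked genes alike, so leaving out genes chosen for many UMIs was likely to lower the excess in any case. No removal of other genes served as a reference. A few abundant genes therefore stay open as an explanation, although the excess left in library 2 does not come from these 10. Gene length stays open, since the files hold no lengths and the difference from matched lists (-0.0743 on the log2 scale in library 2) decides nothing about it.

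Genes raised at least 4-fold tended to have consecutive ID numbers, with 157 pairs whose IDs differ by 1 against 77.3 expected from distant pairs, a ratio of 2.03 where 100 distant differences gave 0.712 to 1.39. At a difference of 2 the ratio was 1.33, within that range but above the narrower range of 0.891 to 1.12 from blocks of 8 differences that was used at first, and at differences of 3 to 10 it was 1.08. The 405 genes lowered at least 4-fold had ratios of 2.27 at a difference of 1 (5 pairs, distant range 0 to 3.63) and 3.81 at a difference of 2 (8 pairs against 2.10 expected, above that range), so the excess is not shown to be particular to raised genes. If the numbers follow the genome, which the files do not state, overlapping models that share reads could raise the closest pairs, but the value at a difference of 2 leaves open whether the excess is limited to them. Adjacent near-identical copies remain open as well at the ratio of 2.03, since the files hold no sequence, and a joint response of neighbouring genes was not tested.

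The shallow barcodes of single-cell library 2 might hold free RNA without a cell, which would make them alike. Over 10 subsets of 600 barcodes, the variance beyond sampling in the 500 most abundant genes was 1.36 ± 0.0807 (SD) times that of deep barcodes of the same library thinned to the same depths. This argues against 1 common pool of free RNA as the whole content of these barcodes, while damaged cells and a mixture of both stay open. In library 1 the ratio was 0.508 ± 0.0421.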
